A study of Mus musculus with 33 samples.

How the data were processed

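The series holds 33 RNA libraries from mouse hippocampal neural stem cells grown in culture with FGF and EGF. Of these, 18 are RNA-seq libraries from cells labelled Nestin-WT or Nestin-cKO for Ythdf2, taken at 0, 2 and 4 h of actinomycin D (5 µM), 3 per genotype and time. A further 6 are an m6A pull-down and its input (3 each), and 9 are a YTHDF2 pull-down, an IgG pull-down and an input (3 each), all from WT cells. The label cKO stands for a conditional knockout.

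Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14, trimmed with Trimmomatic 0.32 and aligned to GRCm38 with STAR 2.5.2a. The tool that counted reads and the gene annotation are not given in the sources used here. For each library the authors deposited a gene count and a TPM value, over 26621 gene symbols. The deposited count values were whole numbers and were used for every model. The deposited TPM values entered a single alternative model. Relative transcript length, used for matching, strata and correlations, came from the ratio of the deposited counts to TPM. Of the symbols, 22003 matched a RefSeq symbol and 24588 matched a symbol or a synonym of the GRCm38.p6 annotation, which gave coordinates.

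For the YTHDF2 pull-down series, the sample titles and the sample descriptions name the Input and YTHDF2 libraries the other way round. The count columns carry the names in the descriptions, and these were used. The titles were kept as an alternative.

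Counts were modelled with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood with TMM scaling, and genes with low counts were removed with filterByExpr at its default settings. Each assay was fitted on its own, over 14029 genes in the RNA-seq libraries, 14167 in the m6A libraries and 14255 in the YTHDF2 libraries. Groups were compared by contrasts within the fit of all libraries of the assay, with 12, 4 and 6 residual degrees of freedom. The difference in decay between genotypes was the genotype difference in a linear slope over 0, 2 and 4 h, in log2 per hour (14 residual degrees of freedom). All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are log2 values with SE. Normalized CPM are counts scaled to the TMM-adjusted library size, given as mean ± SD.

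Gene lists, contrasts, the alternatives of each result and the rule for named genes were fixed before the data were examined. There were 25 lists with 752 genes in all, of 13 to 77 genes each. Each list was tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 25 lists of a comparison. The same tests were run with an estimated correlation, and fry tested whether a list moved one way on balance. Genes were named by rule. For each comparison these were Ythdf2, a fixed set of TGF-beta components, the 8 called genes with the largest change in each direction among those with a mean log2 CPM of at least 4, a symbol that is not a clone or pseudogene name and groups that did not overlap, and the 4 members of each list with the smallest p-values. For target transcripts they were the 8 with the largest rise at 0 h and the 8 with the largest slope difference. Other list members given as examples were picked after their values were seen.

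Target transcripts were defined as genes called higher in the m6A pull-down over input and in the YTHDF2 pull-down over both input and IgG. Their medians in the genotype contrasts were set against 10000 random gene sets matched on expression (10 bins) and transcript length (5 bins), and tested with camera. Overlaps of called genes were tested with Fisher's exact test. Correlations are across genes, which are not independent replicates. Where a pair of contrasts shared libraries, the correlation under no effect was simulated with the same design.

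Replicate numbers were checked for pairing with the correlation of residuals between libraries of different groups. The median was 0.71 within the m6A series, 0.60 within the YTHDF2 series and 0.52 across times within a genotype, and 0.0060 across genotypes. A fit with the replicate number or culture as a block was an alternative for every result. The main fits thus treat libraries paired by number as independent. The labels do not say whether the replicates of a genotype came from separate animals. No near-identical pair of libraries was found.

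The other alternatives were DESeq2 1.42.0, RLE factors, library size alone, no low-count filter, limma on log2(TPM + 1), scaling to ribosomal protein genes, the 6 compared libraries alone, and each library left out in turn. Alternatives added later left out whole cultures, joined the block with other choices, and varied how targets were defined and matched. A definition of targets by enrichment above a log2 of 1 left 3 genes and was not tested.

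The calls were tested on simulated data with the dispersions and depths of each fit. Few genes changed in each simulation, 66 or 67 per size in the group contrasts. The shares called may thus be lower than in data where more genes change. A log2 change of 1 was called in 28.4% of changed genes for the genotype contrast at 0 h, 26.9% and 29.9% for the 4 h contrasts in WT and cKO, 94.0% for m6A, 50.7% for YTHDF2 over input and 44.8% for YTHDF2 over IgG. A log2 change of 2 was called in 92.4%, 90.9%, 90.9%, 100%, 97.0% and 98.5%, and a change of 0.5 in 1.49%, 0%, 0%, 25.4%, 2.99% and 2.99%, in the same order. A slope difference of 0.25 per hour was called in 4% of changed genes and one of 0.5 per hour in 54%.

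Exon usage, peaks and reads over the deleted part of Ythdf2 were not analysed here, since only gene-level values were used.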

Results

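RNA was measured in cultured mouse hippocampal neural stem cells to ask how the m6A reader YTHDF2 shapes their transcripts. The series concerns TGF-beta signalling components and the transition to quiescence. Transcript levels were measured at 0, 2 and 4 h of the transcription inhibitor actinomycin D in libraries labelled WT and cKO (3 each). In WT cells, m6A-carrying RNA was pulled down beside an input (3 each), and RNA bound to YTHDF2 was pulled down beside IgG and an input (3 each). Total counts per library were 10257329 to 21353383 for RNA-seq, 12892222 to 28334300 for the m6A series and 8419106 to 23097887 for the YTHDF2 series. The p-values come from edgeR quasi-likelihood fits with Benjamini-Hochberg adjustment and measure the spread between these libraries.

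Ythdf2, the gene the labels name as deleted, was the first check of the genotype. It lies on chromosome 4 from 132184916 to 132212256 (GRCm38.p6). Its counts went against the label. At 0 h the libraries labelled cKO held 1629 ± 1297 normalized CPM of Ythdf2 (SD, n = 3) and those labelled WT 243 ± 21.4 (SD, n = 3), a log2 difference of 2.74 (SE 0.37, adjusted p = 2.7e-04). The cKO-labelled libraries stayed near this level at 2 h (1196 ± 99.3) and at 4 h (1404 ± 37.0), while WT fell to 74.6 ± 11.7 and 70.6 ± 15.6. In the plot of Ythdf2 counts by library, the 0 h library of culture 1 labelled cKO was the highest, at 3117 CPM. Gene-level counts cannot show whether exons are missing from the transcript. Genotypes are therefore given below as labelled.

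**Figure D1:**
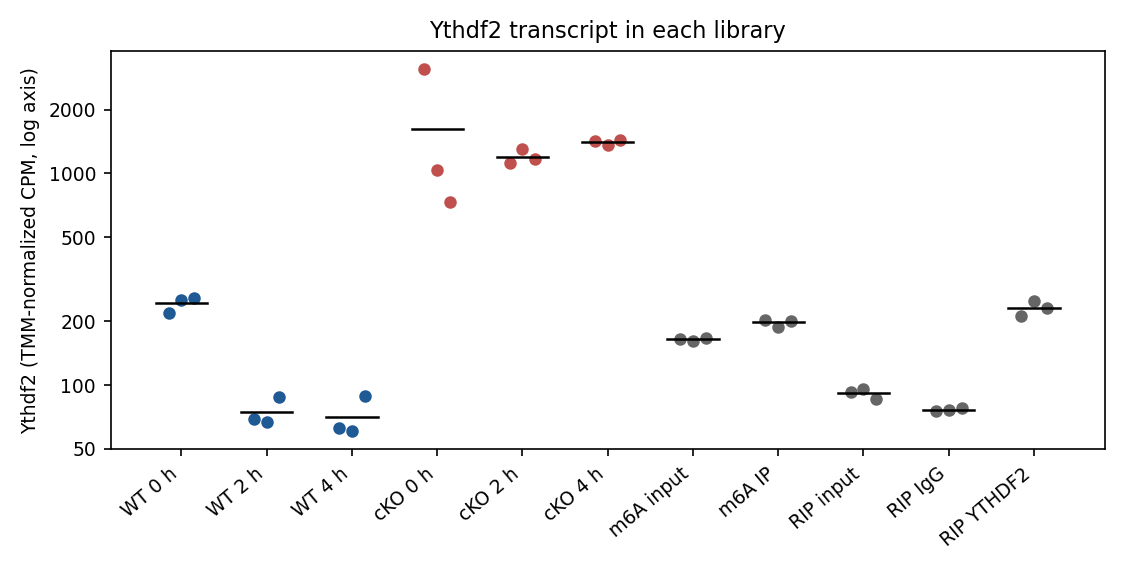
Normalized CPM of Ythdf2 (log axis) in each library, by genotype label and hour of actinomycin D and in the pull-down series, with group means. The lowest library labelled cKO at 0 h has 736 CPM, above all libraries labelled WT.

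The genotype contrast at 0 h asked which transcripts differed before transcription was blocked. Of 14029 genes, 1082 were higher and 1387 lower in the libraries labelled cKO, 673 and 826 of them by more than 2-fold. In 41.3% of genes the groups did not overlap, where chance gives 10%. Mmp3, a matrix metalloproteinase, rose by 6.26 log2 (SE 0.62), from 0.543 ± 0.254 to 42.7 ± 23.0 CPM. Six3, a forebrain transcription factor, had the largest rise at 7.34 log2, but the cKO-labelled culture 1 held 0.662 CPM beside 119 CPM in the highest culture. Other large rises were Sp8 (4.76), the collagen Col5a2 (4.71) and the cytoskeletal linker Plec (3.04). The protocadherin gene Pcdh15 fell by 3.93 log2 from 158 ± 8.49 to 10.4 ± 0.973 CPM (SD, n = 3 each). Rlbp1 (−3.62), the G protein subunit Gng3 (−3.58), Pcdh11x (−2.95), the stem cell surface gene Prom1 (−2.87) and Pdgfra (−2.81) fell as well.

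TGF-beta pathway genes moved in both directions at 0 h. Of 27 tested ligands, receptors and SMADs, 5 rose, 4 fell and 18 did not pass, with 8 higher and 5 lower adjusted over the list alone. The ligand Tgfb2 rose from 60.6 ± 5.07 to 97.0 ± 20.9 CPM (log2 0.68, adjusted p = 0.0461), a call that ended without any of the 3 WT libraries or cKO-labelled replicate 1 or 2 (adjusted p = 0.0630 to 0.144). The receptor Tgfbr1 fell (−1.01, adjusted p = 0.00575). The corepressor Ski rose (1.13) and its relative Skil fell (−0.93), and the ubiquitin ligase Smurf2, which degrades SMADs and receptors, fell (−0.70). The activin subunit Inhba (4.27) and the latency proteins Ltbp1 (0.96) and Ltbp3 (1.31) rose. Smad3 (0.65, adjusted p = 0.0861), Tgfbr2 (1.85, adjusted p = 0.0621), Smad7 (adjusted p = 0.120), Smad2 (−0.11) and Smad4 (−0.01) did not pass, and Tgfb1 was too low to test. As a whole the list did not differ from other genes (camera adjusted p = 0.324).

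**Figure D2:**
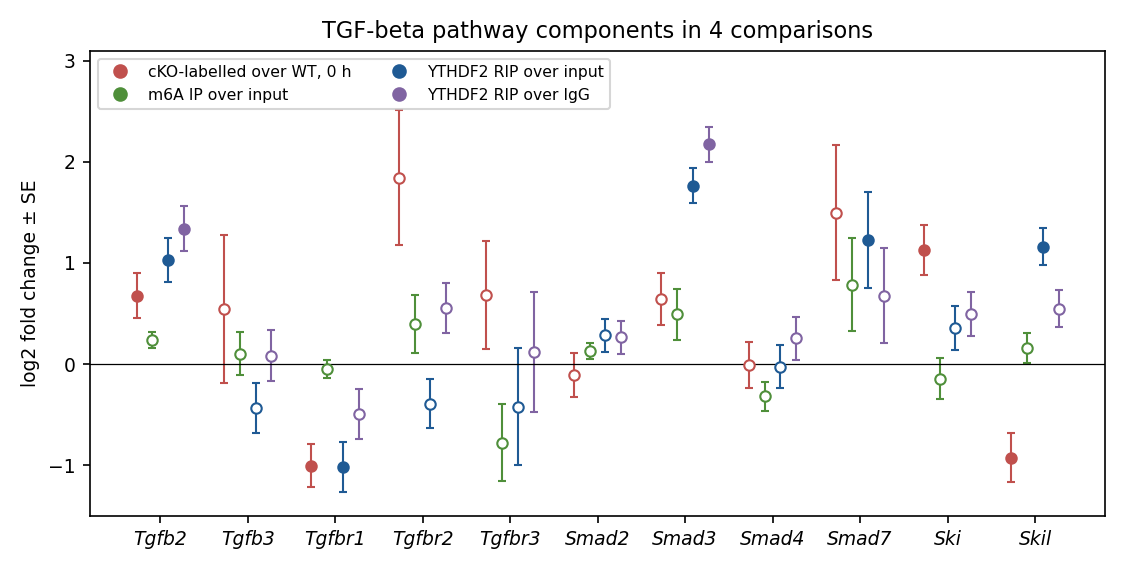
Log2 fold change with SE of TGF-beta pathway genes in each comparison, with filled markers for adjusted p under 0.05. Smad3 and Tgfb2 lie above 0 in the YTHDF2 pull-down over both input and IgG, at 1.76 and 1.03 over input.

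With camera, TGF-beta response genes and fibroblast markers were higher than other genes as lists. Among 29 TGF-beta response genes 12 rose and 2 fell (16 and 2 adjusted over the list alone; median 1.45, camera adjusted p = 7.2e-04; adjusted p = 0.511 with an estimated correlation), led by the collagens Col1a1 (5.35) and Col3a1 (4.19) and the matricellular genes Ctgf (4.72) and Postn (3.54). Fn1 (−1.49) and Timp3 (−1.34) fell. All 13 tested fibroblast and meningeal markers had positive changes, with 8 called over all genes and 13 adjusted over the list alone (median 3.54, camera adjusted p = 5.9e-06; adjusted p = 0.259 with an estimated correlation). Lum (5.75) and Dcn (4.87) had the smallest p-values, and 4 members (Col1a1, Col1a2, Col3a1 and Postn) are in both lists. The median of the fibroblast list lay 1.45, 2.67 and 3.43 above WT in cultures 1, 2 and 3 labelled cKO. In the BMP list of 20 genes, Bmp2 (3.66), the decoy receptor Bambi (3.41), Id1 (2.58), Crim1 (2.27) and Id3 (1.27) rose and the receptor Bmpr2 fell (−1.02), with camera adjusted p = 0.103.

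Oligodendrocyte and astrocyte markers were lower as lists at 0 h. Of 14 oligodendrocyte lineage markers 7 fell and 1 rose, with the same counts adjusted over the list alone (median −1.82, camera adjusted p = 0.00104; adjusted p = 0.171 with an estimated correlation). Gpr17, a receptor of committed precursors, fell by 6.65, and Enpp6 (−4.36), Pdgfra and the myelin gene Mbp (−2.78) fell too, while Olig1 rose (0.94). Of 17 mature astrocyte markers 6 fell and 2 rose, the same adjusted over the list alone (median −0.60, camera adjusted p = 0.0495; adjusted p = 0.259 with an estimated correlation), among them the connexin Gjb6 (−6.20), Agt (−2.16) and the glutamate transporter Slc1a2 (−1.74). Of the neuronal markers, the migration gene Dcx (−2.63) and the transcription factors Neurod6 (−6.61) and Neurod1 (−2.94) fell, and Dlx1 (6.64), Dlx2 (3.30) and Sp8 rose. That list had 4 of 20 genes called in each direction, 5 in each adjusted over the list alone (camera adjusted p = 0.205).

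Stem cell state genes changed singly. Among 38 markers of quiescent neural stem cells 4 rose and 6 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.417). The Notch effector Hes5 (−3.90) and Prom1 fell, and Sparc (1.32) and Nfix (0.72) rose. Of 45 proliferation genes 1 rose (Ccnd1, 1.06) and 2 fell (Aurka, −1.72, and Kif20a, −1.74), with 0 in either direction adjusted over the list alone. The median of that list was −0.65 (camera adjusted p = 0.00181; adjusted p = 0.604 with an estimated correlation). In culture 3 labelled cKO the list's median lay at −1.82 from WT, and in cultures 1 and 2 at −0.29 and −0.40. Among progenitor transcription factors, Tead2 (2.77), Emx2 (1.15) and Lhx2 (0.91) rose and Pax6 (−1.18) and Dll3 (−2.25) fell (3 and 2 of 19; 5 and 3 adjusted over the list alone; camera adjusted p = 0.220). The Wnt and Notch list of 35 had 7 higher and 4 lower (8 and 6 adjusted over the list alone, camera adjusted p = 0.324), with the Notch ligand Jag1 up from 19.2 ± 0.722 to 116 ± 5.27 CPM (log2 2.59).

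Immediate early genes and p53 targets were higher as lists at 0 h. Of 35 immediate early and short-lived transcripts 12 rose and 1 fell (16 and 2 adjusted over the list alone; median 1.01, camera adjusted p = 6.2e-09; adjusted p = 0.0384 with an estimated correlation). They included Jun (1.45), Fosl2 (1.40), the feedback inhibitor Spry2 (1.84) and Ier3 (2.00). Of 25 p53 targets 8 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0273; adjusted p = 0.604 with an estimated correlation). Among them were the cell cycle inhibitor Cdkn1a (1.77), Mdm2 (1.22), Perp (3.27) and Gdf15 (4.53). The median of the p53 list lay 0.11, 0.20 and 0.86 above WT in cultures 1, 2 and 3 labelled cKO.

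With camera, nuclear oxidative phosphorylation and ribosomal protein genes were higher and zinc finger genes lower than other genes as lists. Of 50 nuclear oxidative phosphorylation genes 28 rose and 0 fell (38 and 0 adjusted over the list alone; median 0.50, camera adjusted p = 2.2e-15; adjusted p = 0.146 with an estimated correlation), for example Ndufa4 from 818 ± 49.7 to 1350 ± 102 CPM and Atp5g3 (1.44). Without single libraries the oxidative phosphorylation calls ranged from 12 to 35, with 12 or 13 without any WT library. Of 76 ribosomal protein genes 14 rose and 0 fell, the same adjusted over the list alone (median 0.24, camera adjusted p = 2.8e-07; adjusted p = 0.511 with an estimated correlation), among them Rps2 (1.04) and Rps10 (1.06). The ribosomal calls numbered 3, 2 and 3 without WT replicate 1, 2 or 3, and 4 and 24 without replicate 2 or 3 labelled cKO. By culture labelled cKO the ribosomal median was 0.35, 0.39 and −0.041. Of 53 C2H2 zinc finger genes 0 rose and 22 fell (0 and 34 adjusted over the list alone; median −0.89, camera adjusted p = 8.1e-14; adjusted p = 0.0384 with an estimated correlation), such as Zfp40 (−1.45), Zfp60 (−1.73) and Zfp157 (−1.43). Glycolysis genes had 1 higher and 5 lower of 20 (2 and 5 adjusted over the list alone, camera adjusted p = 0.220), with Pdk1 (−1.68), Ldha (−1.26) and Pgk1 (−0.91) falling and Hk1 rising (1.15). By culture labelled cKO their median was −0.94, 0.018 and −0.021.

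**Figure D3:**
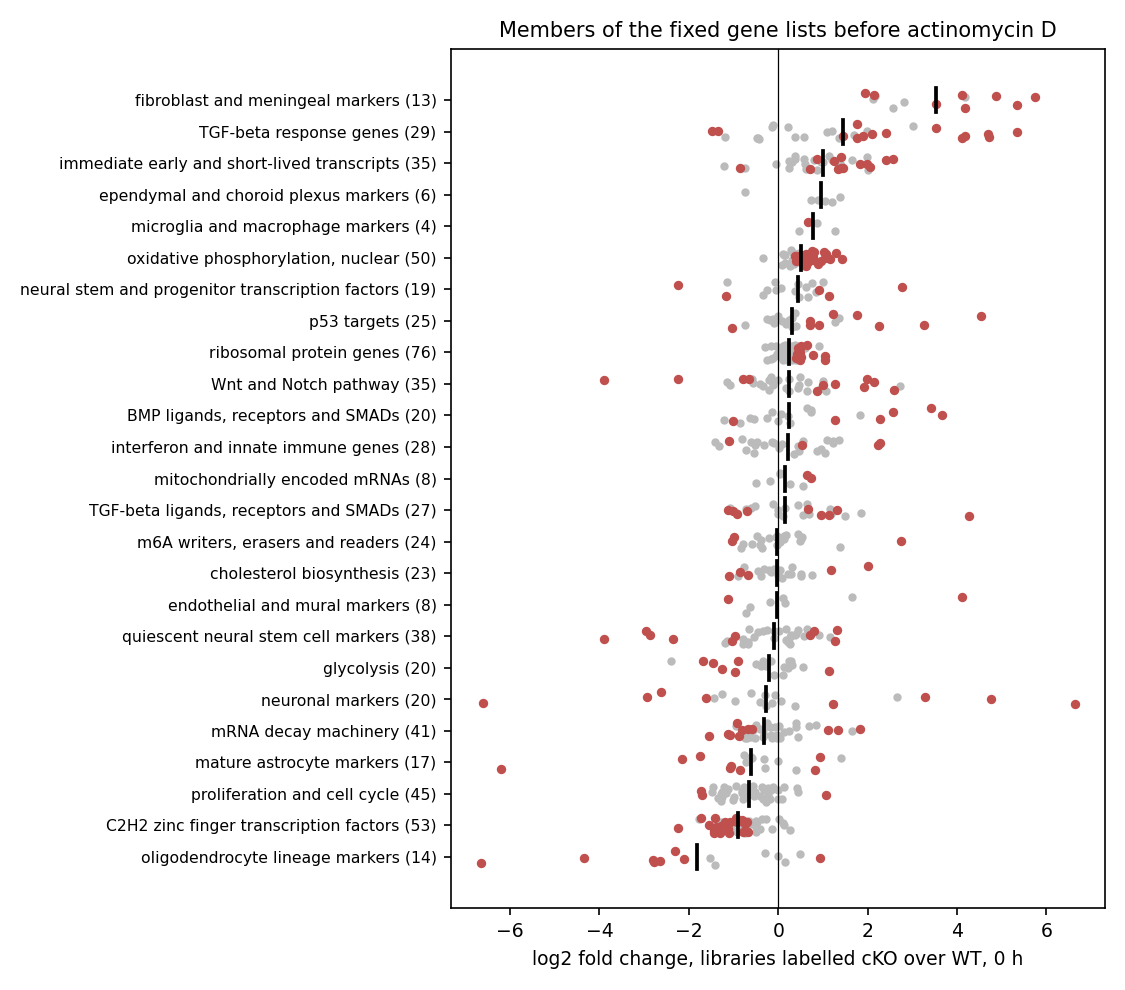
Log2 fold change at 0 h (libraries labelled cKO against WT, 3 each) of the genes of each fixed list, with list medians. Medians range from −1.82 for oligodendrocyte lineage markers to 3.54 for fibroblast and meningeal markers.

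RNA regulators changed little as groups. Of 24 m6A writers, erasers and readers, only Ythdf2 rose, and the methyltransferase Mettl3 (−0.99, adjusted p = 0.0208) and Cbll1 (−1.04) fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.599). Of 41 decay genes 3 rose and 8 fell (3 and 9 adjusted over the list alone, camera adjusted p = 0.224). The AU-rich element binder Zfp36l1 rose (1.82), while the nonsense-mediated decay gene Upf2 (−1.55) and the deadenylase scaffold Cnot1 (−1.12) fell. Cholesterol genes had 2 higher and 3 lower of 23 (3 and 3 adjusted over the list alone, camera adjusted p = 0.965), with Hmgcs1 down (−0.86). Interferon genes had 3 higher and 1 lower of 28 (1 and 0 adjusted over the list alone, camera adjusted p = 0.347), with the chemokine Ccl2 up (2.29). Mitochondrially encoded mRNAs had 2 of 8 higher (camera adjusted p = 0.145). Microglial markers, 4 of them tested, did not differ from other genes as a list (camera adjusted p = 0.113). Endothelial markers had Vtn higher (4.12) and Mcam lower (−1.12) of 8, with a median of −0.03 and a mean of 0.42 (camera adjusted p = 0.830). Ependymal markers had 0 of 6 called (camera adjusted p = 0.324).

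Counts at 0 h depended on single libraries: without WT replicate 1, 2 or 3, 306, 429 and 332 genes were higher and 633, 686 and 567 lower, and without replicate 3 labelled cKO 779 were lower. Without the whole cKO-labelled culture 1, 1971 were higher and 2351 lower, and without culture 2, 529 and 730. From TPM the split was 1023 and 2429, and with DESeq2 it was 1712 and 1699.

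Loss of RNA under actinomycin D was followed in WT to see which transcripts were unstable. Between 0 and 4 h, 2194 genes rose and 3402 fell relative to the other transcripts, 682 and 2770 of them by more than 2-fold. The small GTPase Rasl11a fell by 5.64 log2, from 123 ± 12.7 to 2.49 ± 0.706 CPM. The kinases Plk2 (−5.42) and Sgk1 (−5.42), Myc (−4.76) and the repressor Bhlhe40 (−4.65) fell likewise. The glycolytic genes Pkm2 (1.55), Pdk1 (1.55) and Pfkl (1.47), the mitophagy gene Bnip3 (1.71) and the deacetylase Sirt2 (1.61) gained share. These changes are relative to the other transcripts, so the scaling sets their balance. The median of all genes was 0.0049 with TMM, −0.33 with library size, −0.32 from TPM and −0.73 with ribosomal protein genes as reference. The matching splits were 698 higher and 4412 lower with library size, 342 and 5179 from TPM, and 44 and 6027 with the ribosomal reference. With the replicate number as a block 3332 rose and 4084 fell.

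Immediate early and zinc finger transcripts had the lowest list medians in WT. All 32 immediate early and short-lived transcripts called of 35 fell (33 adjusted over the list alone; median −3.53, camera adjusted p = 9.7e-15; adjusted p = 0.00935 with an estimated correlation), among them Ier5 (−6.04) and Socs3 (−4.65). Of 53 C2H2 zinc finger genes 47 fell (49 adjusted over the list alone; median −2.08; adjusted p = 0.0112 with an estimated correlation), such as Zfp105 (−4.46). Of 27 TGF-beta ligands, receptors and SMADs 14 fell and 2 rose (16 and 2 adjusted over the list alone; camera adjusted p = 0.0118; adjusted p = 0.192 with an estimated correlation). Tgif1 (−3.28), Tgfbr2 (−2.79), Skil (−2.28) and Tgfbr1 (−2.04) fell and Ltbp3 rose (1.23). Progenitor factors (13 of 19 fell, 1 rose; Sox2, −3.31), the Wnt and Notch list (20 of 35 fell, 2 rose; Hes1, −3.82), decay genes (20 of 41 fell; Btg1, −3.55) and m6A genes (11 of 24 fell, 2 rose; Ythdf1, −2.59, and Ythdf2, −1.78) were also lower than other genes, with adjusted p from 0.121 to 0.214 with an estimated correlation. Nuclear oxidative phosphorylation genes (48 of 50 rose), ribosomal protein genes (73 of 76) and glycolysis genes (13 of 20; Aldoa, 1.19) rose, as did quiescence markers (16 of 38 rose, 4 fell; Apoe, 1.23) and astrocyte markers (6 of 17; Acsbg1, 1.29), with adjusted p from 0.0669 to 0.168 with an estimated correlation. The quiescence list turned to a median of −0.01 with ribosomal protein genes as reference.

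In the libraries labelled cKO, 1694 genes rose and 2528 fell between 0 and 4 h, 406 and 2062 by more than 2-fold. Rasl11a (−6.56), Sgk1 (−6.35), Bhlhe40 (−6.01), Plk2 (−5.88), the phosphatase Dusp6 (−5.80), Spry2 (−5.36) and Myc (−5.31) fell most. Pkm2 (1.72), the autophagy gene Atg7 (1.55) and the serine synthesis gene Phgdh (1.48) rose. Ythdf2 itself did not pass (−0.21, adjusted p = 0.680). It fell from 3117 to 1418 CPM in culture 1 but rose from 1035 to 1362 and from 736 to 1432.5 CPM in cultures 2 and 3. The same 2 lists led the falls, with 34 of 35 immediate early transcripts (34 adjusted over the list alone; median −4.18; adjusted p = 5.7e-04 with an estimated correlation) and 47 of 53 zinc finger genes (49 adjusted over the list alone; adjusted p = 0.00829 with an estimated correlation). The BMP list fell too (8 of 20; Bmp2, −5.81, and Id1, −3.99; adjusted p = 0.0319 with an estimated correlation). Of 8 mitochondrially encoded mRNAs 5 fell (camera adjusted p = 0.00158; adjusted p = 0.0919 with an estimated correlation), among them mt-Nd2 (−1.07). The other lists called were lower for TGF-beta components (12 of 27), decay genes, progenitor factors and the Wnt and Notch list, and higher for oxidative phosphorylation (43 of 50), ribosomal protein (70 of 76), glycolysis (10 of 20, with 1 lower) and astrocyte genes (4 of 17), for which adjusted p was 0.0729 to 0.285 with an estimated correlation. With the ribosomal reference the medians of the oxidative phosphorylation (−0.05), glycolysis (−0.13) and astrocyte lists (−0.12) turned negative. Both genotypes shared 2168 falls, where independent lists would share 623, and 1178 rises, where they would share 273. Across genes the 4 h changes correlated at r = 0.836.

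Scaling, the libraries in the fit and single cultures moved the cKO-labelled counts. The median of all genes was 0.083 with TMM, −0.15 with library size (515 higher, 3169 lower), −0.21 from TPM (278 and 3841) and −0.65 with the ribosomal reference (31 and 5479). With the replicate number as a block 2966 rose and 3239 fell. The 6 compared libraries alone gave 149 rises and 1298 falls, and 721 and 1809 with the block as well. Without the 4 h library of culture 2, 887 genes were higher, and without culture 2 as a whole 622 were higher and 1665 lower.

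The difference in slope between genotypes asked which transcripts were lost at another rate in the libraries labelled cKO. Without the culture as a block it was significant for a single gene of 14029. Bag5, a chaperone cofactor on chromosome 12 (111709488 to 111713256), was lost more slowly, with a difference of 0.37 log2 per hour (SE 0.06, adjusted p = 0.0315). Its level fell from 113 ± 7.51 to 47.3 ± 5.36 CPM in the libraries labelled cKO and from 106 ± 9.44 to 15.7 ± 2.29 CPM in WT (SD, n = 3 each). For Ythdf2 the difference was 0.39 per hour (SE 0.13, adjusted p = 0.361). At an unadjusted p under 0.05 there were 1184 genes, and DESeq2 called 45 slower and 19 faster. The Bag5 call held without the 0 h replicate 1 of either genotype or the 2 h replicate 1 or 3 labelled cKO, and ended without any other of the 18 libraries (adjusted p up to 0.288), with RLE factors (0.0604), with no low-count filter (0.0865) and with the ribosomal reference (0.0566). With the culture as a block 65 genes were lost more slowly and 24 faster, among them Gemin4 (0.54), the phosphodiesterase Pde4d (0.47) and Asb8 (0.39), and Enc1 (0.55) outside the targets, while Chst2 (−0.38) was lost faster. Without WT culture 1, 2 or 3 the blocked fit called 0 genes in either direction, and without cKO-labelled culture 1, 2 or 3 it called 295, 10 and 12 slower and 184, 3 and 11 faster.

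Among the fixed lists, 8 differed in slope from other genes with camera and 0 with an estimated correlation. No member of them passed over all genes. Cholesterol genes (median −0.098 log2 per hour, camera adjusted p = 8.6e-08; adjusted p = 0.186 with an estimated correlation; 3 lower adjusted over the list alone, such as Insig1) and mitochondrially encoded mRNAs (median −0.14; adjusted p = 0.102 with an estimated correlation; 4 lower adjusted over the list alone) had the smallest p-values. Immediate early genes (−0.15), quiescence markers (−0.081), astrocyte markers (−0.064), glycolysis (−0.048) and oxidative phosphorylation genes (−0.033) were lower in slope as lists, and progenitor factors higher (0.15), with adjusted p from 0.284 to 0.646 with an estimated correlation. Slopes of TGF-beta components (median 0.076) did not differ from other genes (camera adjusted p = 0.520). Slope and 0 h differences share the 0 h libraries. They correlated at r = −0.299 across genes, where simulation without any effect gave −0.710. The covariance was −0.056, beside −0.053 in the simulation.

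The m6A pull-down was compared with its input to find transcripts that carry the mark. Of 14167 genes 858 were enriched and 2023 depleted, 13 and 448 by more than 2-fold. The transcription factor gene Jun rose from 168 ± 11.4 to 363 ± 101 CPM (log2 1.11). The poly(ADP-ribose) glycohydrolase Parg (0.84), Dusp6 (0.81), the scaffold Akap12 (0.82), the adhesion gene Nlgn3 (0.80) and the BMP antagonist Smoc1 (0.79) were enriched too. The ribosomal protein gene Rps14 fell from 799 ± 40.2 to 152 ± 10.9 CPM (−2.39), and Lgals1 by 2.37. In the TGF-beta list the coreceptor Eng (1.36, a call that ended without any single library) and the integrin Itgb8 (0.41) were enriched of 29 (1 adjusted over the list alone, camera adjusted p = 0.148). Tgfb2 (0.24, adjusted p = 0.0525) and Smad3 (0.49, adjusted p = 0.211) did not pass, but did with the replicate number as a block (adjusted p = 7.8e-04 and 1.6e-06), where 6 of the list were enriched and 1 depleted. Ythdf2 was enriched (0.27, adjusted p = 0.0213).

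Ribosomal and mitochondrial genes were depleted from the m6A pull-down. All 76 ribosomal protein genes (median −1.57), 47 of 50 oxidative phosphorylation genes (−1.05) and all 8 mitochondrially encoded mRNAs (−1.20) fell, with 76, 49 and 8 adjusted over the list alone (adjusted p = 0.338, 0.302 and 0.302 with an estimated correlation). Of 53 zinc finger genes 10 were enriched (16 adjusted over the list alone; median 0.28, camera adjusted p = 4.8e-09; adjusted p = 0.837 with an estimated correlation), such as Zfp180 (0.53). Glycolysis genes (9 of 20 lower, 2 higher; Gapdh, −1.32) and proliferation genes (10 of 45 lower; Cdk4, −1.01) were lower as lists (adjusted p = 0.945 for both with an estimated correlation). Enrichment rose with transcript length across genes (r = 0.471). The median of all genes was 0.0096 with TMM, 0.22 with library size (3627 higher, 1293 lower) and 0.40 from TPM (7236 and 770), and DESeq2 gave 1269 and 2036. With the replicate number as a block 2441 were enriched and 2932 depleted. The proliferation median turned to 0.02 with library size and 0.28 from TPM, and the glycolysis median to 0.16 from TPM. Without input 1, pull-down 1, input 3 or pull-down 3, 557, 370, 343 and 347 genes were enriched.

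The YTHDF2 pull-down was compared with its input and with IgG to find bound transcripts. Over input 4373 of 14255 genes were higher and 2490 lower. Over IgG 2040 were higher and 47 lower. With the replicate number as a block these were 5549 and 3526 over input and 3134 and 1268 over IgG (3349 and 3567 from the 6 libraries compared). The zinc finger gene Zfp273 rose from 14.5 ± 1.47 to 148 ± 12.3 CPM over input (log2 3.35) and by 3.31 over IgG. The methionine adenosyltransferase Mat2a (2.98 over input) and Gemin7 (3.43 over IgG) were also enriched. The mitochondrial genes mt-Cytb (−3.36) and mt-Nd4 (−2.94) and the ribosomal protein gene Rplp0 (−2.64) were depleted over input. Ythdf2 was bound as well (1.34 over input, 1.60 over IgG). IgG over input itself had 2873 genes higher and 2422 lower. YTHDF2 and IgG enrichment over the shared input correlated at r = 0.718, where simulation without any effect gave 0.508. Both YTHDF2 contrasts shared 1579 higher genes, where independent lists would share 626. They have the pull-down libraries in common, and across genes they correlated at r = 0.455, where simulation without any effect gave 0.480. The covariance was 0.296, beside 0.059 in the simulation, where 0 higher genes were shared.

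Single TGF-beta transcripts were among those bound. Smad3 rose from 110 ± 8.61 in input to 372 ± 62.2 CPM in the pull-down (log2 1.76, SE 0.17) and stood at 82.5 ± 8.15 CPM with IgG, a difference that was called as well, Tgfb2 by 1.03 (adjusted p = 0.0025) and 1.34 (adjusted p = 0.0011), and the corepressors Tgif1 (1.51 and 0.88) and Tgif2 (1.18 over IgG) in both contrasts. Over input Skil (1.16), Smad7 (1.23), Smurf2 (0.78) and the receptor Acvr2a (0.77) were higher and Tgfbr1 lower (−1.02). The list had 10 higher and 1 lower of 28 over input (8 and 1 adjusted over the list alone, camera adjusted p = 0.359) and 4 higher over IgG (4 adjusted over the list alone, camera adjusted p = 0.191). Of all 14255 genes, 4373 were higher over input and 2040 over IgG. The list's higher counts were thus near the share of all genes. The BMP genes Bambi (2.03 and 2.70) and Acvr1 (1.44 and 1.45) were bound in both contrasts.

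Zinc finger transcripts were the list most enriched with YTHDF2. Over input 43 of 53 were higher and 1 lower (46 and 1 adjusted over the list alone, camera adjusted p = 5.4e-10; adjusted p = 0.650 with an estimated correlation). Over IgG 33 were higher (41 adjusted over the list alone, camera adjusted p = 4.5e-15; adjusted p = 0.931 with an estimated correlation), such as Zfp433 (2.48 and 2.54). Over input the lists of oxidative phosphorylation (34 of 50 lower), ribosomal protein (34 lower and 6 higher of 76), mitochondrially encoded (7 of 7 lower), cholesterol (14 lower and 1 higher of 23), glycolysis (10 lower and 1 higher of 20; Aldoa, −1.44), quiescence (12 lower and 4 higher of 37; Mt3, −1.57) and astrocyte genes (5 lower and 2 higher of 16) were lower than other genes, with adjusted p from 0.466 to 0.857 with an estimated correlation. Over IgG oxidative phosphorylation, ribosomal protein and proliferation genes were lower as lists with 0 members called (adjusted p = 0.931 for each with an estimated correlation). The median of all genes over input was 0.23 with TMM, 0.057 with RLE factors (3545 higher, 3211 lower), 0.32 with library size and 0.45 from TPM (5980 and 1233), and DESeq2 gave 3740 and 3402. Over IgG it was −0.077, and −0.20 with RLE factors (1752 higher, 326 lower) and DESeq2 (2017 and 801). Without pull-down 2, IgG 2, pull-down 3 or IgG 3, the lower genes over IgG numbered 11, 10, 30 and 16.

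Target transcripts, m6A-enriched and bound by YTHDF2 over both input and IgG, joined the 3 assays. Of 13087 genes tested in all assays, 853 were m6A-enriched, 1543 bound and 360 both, where 101 would be shared by independent lists (odds ratio 6.82, 95% confidence interval 5.86 to 7.93, Fisher's exact test). Within strata of expression and length the odds ratio was 5.65 (4.84 to 6.59). Ythdf2 is itself a target by this definition, and so are Bag5, Gemin4, Asb8, Pde4d and the helicase gene Ddx6. Tgfb2 and Smad3 are not, since they were bound but did not pass for m6A without the block. With the replicate number as a block in the pull-down fits, a definition added later, 1090 genes are targets, Tgfb2 and Smad3 among them. Of the m6A-enriched genes 418 fell by 4 h in WT, where independent lists would share 216.

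As a set, target transcripts had a lower median at 0 h and a higher median slope in the libraries labelled cKO. Their median genotype difference at 0 h was −0.30, where matched random sets had a median of −0.13 (central 95%, −0.22 to −0.05), with 10 of them higher and 68 lower, where 27.2 and 36.8 would be by chance. Zfp60 (−1.73), Sybu (−1.66) and Pde4d (−1.65) were among the lower targets, and Ythdf2, Fam84a (2.31), Lrrn2 (1.17) and the fucosyltransferase gene Fut8 (1.01) among the higher. The camera p was 2.2e-04, and 0.0551 with an estimated correlation. Without the 0 h library of culture 1 labelled cKO the median was −0.23 beside −0.18 in matched sets, inside their central 95%, so this result ended. Without genes named as zinc fingers, 314 targets had a median of −0.23 beside −0.13 in matched sets, with 10 higher and 47 lower (p = 0.122 with an estimated correlation). The 1090 targets of the blocked fits had −0.26 beside −0.11, with 208 lower, and 68 higher where 82.4 would be by chance, which did not pass (Fisher's exact test p = 0.0935). The median slope difference of targets was 0.089 log2 per hour, where matched sets had 0.025 (0.0097 to 0.041), and 75.6% of targets had a positive difference beside 55.0% of other genes. The camera p was 2.5e-08, and 0.0106 with an estimated correlation. Single target genes rarely passed, with Bag5 as the one called. The 314 and the 1090 targets had median slopes of 0.096 and 0.073. With the culture as a block the median was 0.081 and 11 targets were slower and 0 faster. Without any single library or any cKO-labelled culture the slope median of targets lay above all matched sets. Both results rest on the descriptions of the YTHDF2 series. Library composition, looked at later, argues against the titles. Rnr2 made up 3.79 to 5.93% of counts in the libraries described as Input and 2.47 to 3.04% in the m6A inputs. It made up 0.28 to 0.39% in those described as YTHDF2 and 0.24 to 0.33% with IgG, which both sources name alike. Mitochondrially encoded mRNAs made up 2.6 to 3.4%, 0.69 to 0.82% and 0.82 to 1.11% in those described as Input, YTHDF2 and IgG. With the titles in place of the descriptions 16 genes are targets, with a median of 0.11 at 0 h beside −0.11 in matched sets. Their slope median was 0.032 beside 0.016, and both medians lay inside the central 95% (percentiles 87.6 and 66.5).

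**Figure D4:**
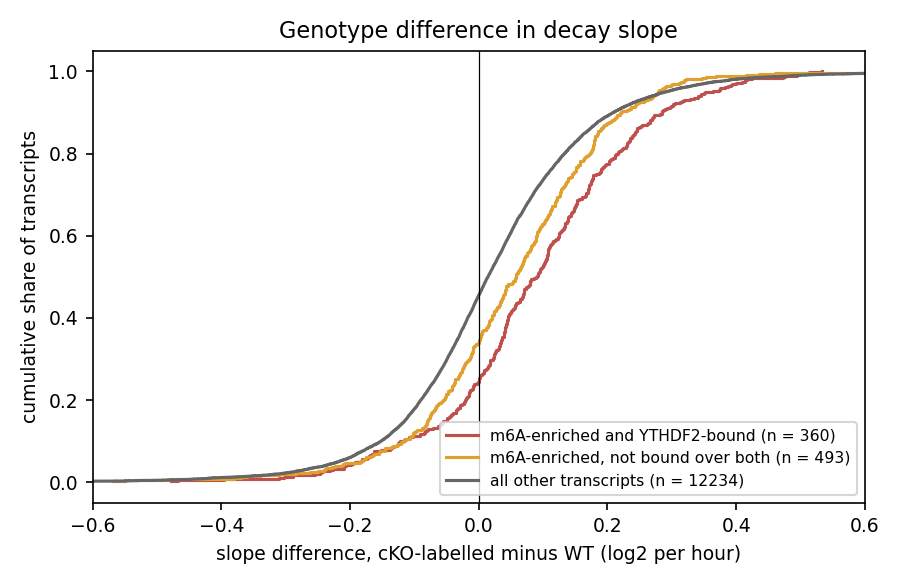
Distribution of the genotype difference in slope (log2 per hour, cKO-labelled minus WT) for target transcripts and other genes. The targets' median is 0.089 and that of other genes 0.016.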

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

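The tests of short-lived transcripts in general and of the shared 0 h libraries, and the fit of the target set with the culture as a block, were chosen after the result was seen.

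Without the culture as a block, the slope of RNA loss under actinomycin D differed between the genotypes by an interaction test for a single gene, Bag5. With the block 65 genes were lost more slowly and 24 faster, and 0 when WT culture 1, 2 or 3 was left out. The lists and the set below were called with camera, which sets a list's genotype difference in slope against that of other genes. Bag5 was lost more slowly in the libraries labelled cKO, by 0.37 log2 per hour. Progenitor transcription factors had a higher median slope (0.15). Lower median slopes were found for immediate early and short-lived transcripts (−0.15), mitochondrially encoded mRNAs (−0.14), cholesterol biosynthesis (−0.098), quiescent neural stem cell markers (−0.081), mature astrocyte markers (−0.064), glycolysis (−0.048) and oxidative phosphorylation genes (−0.033). Transcripts enriched for m6A and bound by YTHDF2 had a higher median slope (0.089). With an estimated correlation none of the 8 lists was called by camera, while the target set had p = 0.0106. With fry 0 lists were called. Immediate early medians lay 1.01, 0.98 and 0.94 above WT at 0 h in the cultures labelled cKO. At 4 h they lay at −3.40, −3.24 and −2.76, beside −3.30, −3.30 and −2.99 in WT. Their lower slope thus came with a higher level at 0 h.

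Target transcripts had a higher median slope in the libraries labelled cKO. A slower loss of short-lived transcripts in general stays open as a cause, in whole or in part. The targets' median of 0.089 lay at percentile 100 of sets matched on expression and the mean 4 h change of both genotypes (median 0.048). It lay at 99.6 of those matched on the 4 h change in WT (0.069, and 97.9 with the culture as a block). Sets matched on length had 0.025. Random sets treat genes as independent, while the estimated correlation among targets was 0.043, so these percentiles cannot decide it. Noise or a lower level in the shared 0 h libraries stays open as well. The genotype difference between 2 h and 4 h uses none of these libraries. There the targets' median lay at percentile 99.99 (camera p = 0.0231; p = 0.210 with an estimated correlation). It lay at 79.3 when sets were matched on the 4 h change in WT, which itself uses libraries of this contrast. Since genes are correlated, these values cannot decide it. Among m6A-enriched transcripts, the 360 targets had a higher median slope difference than matched sets of the other 493 (percentile 99.96). With the culture as a block this was 99.24, or 98.1 when matched on the mean 4 h change. The 493 were not called over both input and IgG, but they are not all unbound. Of the m6A-enriched transcripts 558 were called over input and 426 over IgG. The result goes with slower decay where YTHDF2 is lost, as a hypothesis found and tested on the same data. The targets' level at 0 h goes the other way, since slower decay alone would raise it. Their median there was −0.30, with 10 higher and 68 lower, although this result ended without 1 library. At 4 h their median was 0.035 beside 0.078 in other genes. Their higher slope thus came with a lower level at 0 h. The direction goes with the genotype label, whereas the Ythdf2 counts go against it, and differences between the cultures other than Ythdf2 stay open as untested.

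The 6 cultures can be split in 10 ways, which are too few for a share under 0.05. The real split, 1 of 10, gave 1 gene with a slope difference and the highest other 0. With the culture as a block it gave 89 genes and the highest other 0. For the target set, the distance of the median slope difference from that of all genes was 0.073 in the real split and 0.043 in the highest other. For the other comparisons the 10 splits are likewise too few, and no other split reached the real count. In every comparison the other splits mix libraries of both real groups, which raises the fitted spread. Counts of 0 there are thus close to fixed in advance and give no support. The real and highest other counts were 2469 and 0 for the genotype at 0 h, 5596 and 0 for 4 h in WT, 4222 and 0 for 4 h in cKO, 2881 and 0 for m6A, 6863 and 0 for YTHDF2 over input, and 2087 and 0 for YTHDF2 over IgG. Where the numbers pair the libraries, the 4 splits that part 3 pairs gave 0 apart from the real one.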

How the results depend on the processing

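Settings that joined the block with another choice, or left out whole cultures, were added after the data were seen. Of the values of named genes under other settings, 13973 kept their direction and side of the threshold, 614 were weaker, 487 stronger, 174 moved and 15 reversed. In each case below the cause was not tested. With 3 libraries per group, a log2 change of 0.5 at 0 h was called in 1.49% of changed genes when few genes were simulated to change. Smaller changes than a log2 of 1 were called in the data. Of the 2469 genes called at 0 h, 673 rose and 826 fell by more than 2-fold, and the rest changed by less. A library left alone with 1 partner was assumed to vary like the other groups.

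With DESeq2, 1712 genes were higher at 0 h, 45 and 19 had a higher and lower slope, and 801 were lower over IgG. With RLE factors 0 slopes were higher and 326 genes lower over IgG. With library size alone 11 slopes were higher, 698 genes rose at 4 h in WT and 515 in cKO, the m6A split was 3627 and 1293, and 74 genes were lower over IgG. With no low-count filter 0 slopes were higher and 17 genes lower over IgG. From TPM, 2429 genes were lower at 0 h, 25 and 2 slopes differed, 342 genes rose and 5179 fell in WT, 278 and 3841 in cKO, 7236 and 770 differed for m6A, 1233 were lower over input and 17 over IgG. With ribosomal protein genes as reference 0 slopes were higher, 44 genes rose and 6027 fell in WT, and 31 and 5479 in cKO. With the compared 6 libraries alone 3635 genes rose in WT, 149 rose and 1298 fell in cKO, and 30 were lower over IgG. The interaction at 4 h gave 3 higher slopes and that at 2 h gave 0.

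With the replicate block, 65 slopes were higher and 24 lower, 3332 genes rose in WT and 2966 in cKO, 2441 were m6A-enriched, and 3134 were higher and 1268 lower over IgG. At 0 h, where the numbers do not pair across genotypes, it gave 665 higher and 887 lower. The block with the 4 h interaction gave 199 and 97 slopes, and with the ribosomal reference 23 and 5. The block without any WT culture gave 0 higher slopes, and without cKO culture 1, 2 or 3 it gave 295 and 184, 10 and 3, and 12 and 11. The block with only the 6 libraries gave 4042 rises in WT, 721 in cKO, 4162 genes lower over input, and 3349 higher and 3567 lower over IgG. With titles in place of descriptions, 2490 genes were higher and 4373 lower over input and 2873 lower over IgG. The 16 targets then differed from matched sets by 0.21 at 0 h, reversed, and by 0.016 in slope. Library composition, given above, argues against the titles.

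With an estimated correlation the target p at 0 h was 0.0551, and the lists called were 2 at 0 h, 0 for slope, 2 in WT, 3 in cKO and 0 for m6A, YTHDF2 over input and over IgG. With fry, 0 lists were called for slope and 2 over IgG.

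Leaving out single libraries or cultures gave 306 to 1971 higher and 567 to 2351 lower genes at 0 h, 0 to 18 and 0 to 4 slopes, 1500 to 2172 rises and 2693 to 3004 falls in WT, and 622 to 2321 and 1665 to 2884 in cKO. It gave 343 to 841 and 1477 to 1934 for m6A, 3547 to 4483 and 1898 to 2441 over input, and 1516 to 2183 and 10 to 60 over IgG. The targets' difference from matched sets ranged from −0.19 to −0.052 at 0 h and from 0.045 to 0.083 in slope.

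Named values that reversed at 4 h were Pmvk in WT from TPM (−0.043) and, with the ribosomal reference, Pmvk (−0.28), mt-Co1 (−0.12) and Atp1b2 in cKO (−0.072). Ythdf2 in cKO ranged from −0.58 to 0.67, with 0.67 without the 0 h replicate 1 labelled cKO and 0.66 without that culture. For m6A from TPM, Tgfbr1 (0.40), Bmpr1a (0.32), Vim (0.0064), Cdkn1a (0.15), Xrn2 (0.22), Parn (0.21), Tuba1a (0.13), B2m (0.011) and Nsdhl (0.20) turned positive.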

Other observations

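The genotype contrasts at 2 h and 4 h, the slope test of Ythdf2, the set depleted from m6A and the length test of ribosomal protein genes alone were chosen after the result was seen.

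The genotype difference persisted under actinomycin D in libraries other than those at 0 h, from the same cultures. At 4 h 1549 genes were higher and 1278 lower in the libraries labelled cKO. Of the calls at 0 h, 588 higher and 673 lower genes were called again at 4 h, where independent lists would share 119 and 126, and 495 and 584 were called at all 3 times. Mmp3 was higher by 6.34 log2 at 2 h and 6.62 at 4 h, and Pcdh15 lower, at −4.26 and −4.12. The hypoxia-induced gene Bnip3 was at −1.99, −2.60 and −3.08 at 0, 2 and 4 h. Bag5 was at 0.10, 0.94 and 1.59. Targets of m6A and YTHDF2 had 65 genes higher and 41 lower at 4 h (Fisher's exact test p = 8.0e-05 and 0.202), and 40 and 35 at 2 h (p = 0.0657 and 0.572). As a set they did not differ from other genes at 4 h, with a median of 0.035 beside 0.078 (camera p = 0.582; p = 0.757 with an estimated correlation).

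Fibroblast and meningeal markers differed between the cultures labelled cKO. At 0 h the list median lay at 1.45, 2.67 and 3.43 log2 from WT in cultures 1, 2 and 3, and at 4 h at 1.75, 3.31 and 3.77. Lum reached at most 29.2 CPM and Dcn 14.2 CPM. The 1999 genes depleted from the m6A pull-down had a median of 0.15 at 0 h beside 0.062 in matched sets, with 266 higher and 89 lower (camera p = 5.7e-05; p = 0.0165 with an estimated correlation). Their median slope difference was −0.014 with 0 called (p = 0.0417 with an estimated correlation, and 0.103 with the culture as a block).

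Ythdf2 counts were higher in the libraries labelled cKO. A gain of the region that also covers its neighbours is argued against by the 8 tested genes within 200 kb. Their median log2 difference was −0.076, although Trnau1ap rose by 0.70. Read-through into Ythdf2, or a gain limited to it, need not change the neighbours' levels, so both stay open. An exchange of the genotype labels cannot be told apart from the labels as given: of the genes called at 0 h, the WT inputs of the m6A series lay nearer to the libraries labelled WT for 51.8 to 56.2%, and those of the YTHDF2 series for 36.2 to 39.2%, and these inputs were prepared in other ways. Ythdf2 itself goes against an exchange, at 161 to 166 and 85.8 to 95.8 CPM in these WT inputs, nearer to the 219 to 258 CPM of the 0 h libraries labelled WT than to the 736 to 3117 CPM of those labelled cKO, but as 1 gene across preparations it leaves the exchange open. Transcript of the recombined allele, whose deleted exons are not given in the sources used here, may still be counted and escape decay through YTHDF2, since Ythdf2 is m6A-enriched and bound, but its slope difference of 0.39 per hour did not pass (adjusted p = 0.361).

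Oxidative phosphorylation and ribosomal protein genes were higher and zinc finger genes lower at 0 h in the libraries labelled cKO. A length bias between libraries is argued against for oxidative phosphorylation and zinc finger genes, since 2 of the 3 lists lay outside the central 95% of sets matched on expression and length. For ribosomal protein genes it stays open at 0 h, where they lay at percentile 39.4 of those sets, while at 4 h they lay outside, at percentile 99.77. A general shift from short-lived to long-lived transcripts is argued against by all 3 lists lying outside sets matched on expression and stability. Random sets treat genes as independent, so their ranges may be too narrow. When each of the 6 libraries was left out, 0 of 18 list medians changed sign. A single library labelled cKO is argued against for oxidative phosphorylation (0.44, 0.53 and 0.47 by culture) and zinc finger genes (−0.90, −0.76 and −0.95). It stays open for ribosomal protein genes, at 0.35, 0.39 and −0.041. A difference tied to the genotype or to the cultures stays open as untested.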
